A study of Mus musculus with 16 samples.

How the data were processed

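Whole-kidney gene expression was measured by sequencing of poly(A)-selected RNA from male C57BL/6 mice aged 12 weeks. The labels give 4 groups of 4 libraries. Uninjured mice received vehicle (NV) or PJ34, a small-molecule inhibitor of poly(ADP-ribose) polymerases (NP). Mice that underwent renal ischemia reperfusion surgery, in which blood flow is stopped and then restored, received vehicle (IRV) or PJ34 (IRP). The labels number the replicates but do not say that each came from a separate animal, so the p-values measure the spread between these libraries. The labels do not give the day of tissue collection.

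The deposited table holds expected counts per gene, in whole numbers, for 40472 genes in 16 libraries. Per the submitters' processing notes, the tools were FastQC 0.11.3, Trim Galore 0.6.6, Salmon 1.3.0 and DESeq2 1.30.1, and the genome build was GRCm39. Per the labels' protocols, libraries were made with a directional kit; whether molecular identifiers were used in counting is not given in the sources used here. The authors' counts are not normalised, and their totals differ between libraries. The table holds 6 genes with a total under 3 counts over the 16 libraries, 1871 with a total of 3 and 0 without any count. The counts are whole numbers already, so rounding before the test changed none. Gene symbols were matched by Ensembl ID without its version, for 40276 IDs. The annotation used for names belongs to an older mouse build than the one in the processing notes, so no coordinates are given. Salmon shares reads among similar transcripts, so counts of near-identical genes, such as pseudogenes and members of large receptor families, are uncertain.

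Genes were kept with the filterByExpr function of edgeR at its minimum count of 10, which left 13614 genes. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was run on TMM-scaled counts, with all 16 libraries in 1 fit and the group as the only term. The 5 comparisons were IRV against NV, IRP against NP, IRP against IRV, NP against NV, and the interaction of PJ34 with injury. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, and log2 fold changes carry the standard error implied by the test. CPM values were divided by TMM-scaled library sizes and are given as mean ± SD with n = 4.

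Fixed before the data were examined were the design, the alternative settings except those named below, 29 gene lists and the rule for named genes. That rule took the 8 largest rises and the 8 largest falls per comparison among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups. Unnamed gene models and immunoglobulin or T cell receptor segments were excluded from that part. It further took up to 4 members with the smallest p of each list described, and a preset group of Parp1, Parp2, Cdkn1a, Cdkn2a, Gdf15, Havcr1, Lcn2, Mki67, Col1a1 and Slc34a1. Lists with at least 5 tested members, 28 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The neutrophil list had 4 tested members and was not tested as a list. Some list members that the rule names are not reported here.

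An injury score per library was the mean z-scaled log2 CPM, with a prior count of 2, of the 7536 genes past the threshold for the injury effect averaged over both treatments, with the sign turned for the 4037 lowered genes. The groups were compared by exact permutation over 70 assignments, two-sided, with a smallest possible p of 0.0286. The score genes were chosen on these libraries, so the score's contrast of injured with uninjured groups is not independent evidence, and only differences within injured or within uninjured mice were tested.

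The libraries fell into 2 sets by total count. The 6 deep libraries, which are all IRP libraries and IRV replicates 3 and 4, held 4963638 to 6169748 counts. The 10 shallow libraries, which are all NV and NP libraries and IRV replicates 1 and 2, held 973812 to 1659983. These sets were defined after the data were examined. Every comparison was repeated with the set as a covariate, IRV against NV within the shallow libraries, and IRP against IRV within the deep libraries. IRP and NP share no set, so in that comparison the set can be estimated only through IRV.

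The analysis was tested on simulated counts for the 13614 genes with 200 genes changed. All groups were drawn from a common mean profile with the real library sizes. The simulation thus held no difference in make-up between deep and shallow libraries, and its shares and false calls do not cover that difference. For IRV against NV, 49% of genes changed 2-fold and 75% of genes changed 4-fold were recovered, with 4 false calls. For IRP against NP 49% and 90% were recovered with 4 false calls, for IRP against IRV 53% and 89% with 8, for NP against NV 51% and 83% with 7, and for the interaction 18% and 69% with 4. No pair of libraries within a group agreed within sampling noise, the lowest chi-square per degree of freedom being 1.83. Alternatives covered DESeq2 1.42.0 on all genes and, chosen after the results were seen, on the genes edgeR tested, other scaling factors, other filters, robust dispersion, limma-voom with sample weights, a replicate block, fits of only the 2 groups compared, and leaving out each replicate in turn. Plots and background checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.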

Results

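Gene counts were collected for 16 kidney libraries in 4 groups of 4. Uninjured mice had received vehicle (group NV) or PJ34, which inhibits PARP enzymes (group NP). Mice with ischemia reperfusion injury had received vehicle (group IRV) or PJ34 (group IRP). The study asked how PJ34 acts on the kidney in the longer term after this injury. Total counts ran from 973812 in IRV replicate 1 to 6169748 in IRV replicate 4. The 4 IRP libraries and IRV replicates 3 and 4 held at least 4963638 counts (deep libraries), and the other 10 libraries held at most 1659983 (shallow libraries). Genes of the olfactory, vomeronasal, taste and trace-amine receptor families summed to 306 to 592 CPM in the deep libraries and to 4795 to 9380 CPM in the shallow ones. The difference in depth and receptor counts thus ran through the IRV group and separated all IRP from all NP libraries.

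**Figure D1:**
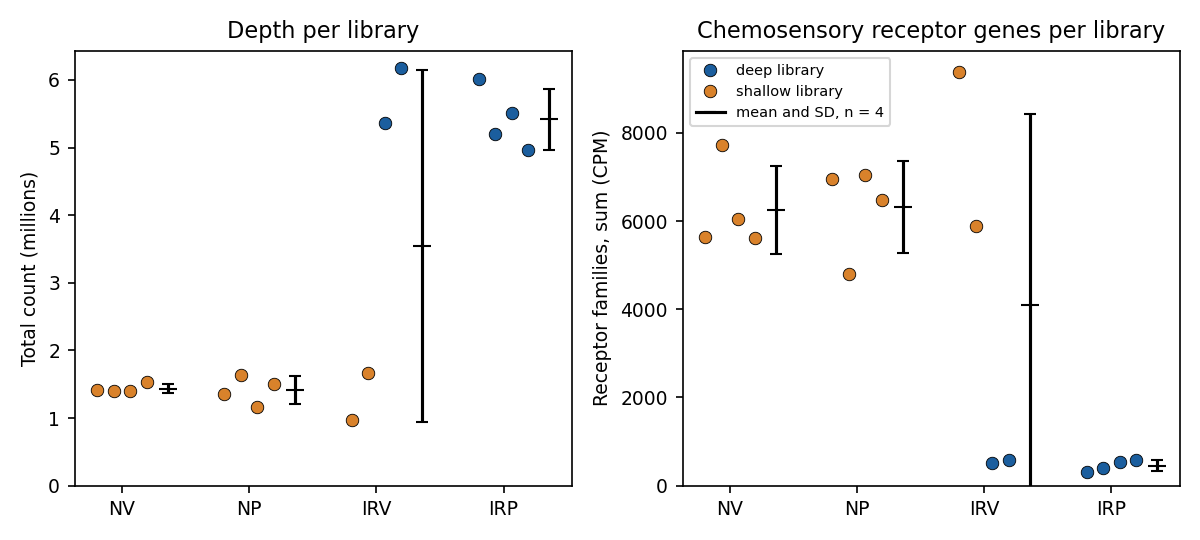
Total count per library in units of 1e6 counts (left) and summed CPM of chemosensory receptor genes (right), by group. Points are libraries coloured by set, bars give mean and SD of 4 libraries, and the 6 deep libraries lie at 4.96 or more on the left axis and 592 CPM or less on the right, the 10 shallow ones at 1.66 or less and 4795 CPM or more.

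The comparison of IRV with NV asked what ischemia reperfusion did without the inhibitor. Markers of injured tubules rose. Havcr1, the kidney injury molecule KIM-1, went from 5.63 ± 4.22 CPM in NV to 110.5 ± 24.2 CPM in IRV (SD, n = 4), a log2 change of 4.34 ± 0.56 (SE; adjusted p = 4.4e-05, edgeR). Lcn2, which encodes the injury marker NGAL, rose by 3.95 ± 0.52, and Spp1, which encodes osteopontin, by 2.15 ± 0.18 from 547.8 ± 63.4 CPM. In the list of tubular injury markers, 21 of 22 tested members rose and none fell, with a median log2 change of 2.17. Dcdc2a rose by 2.82 ± 0.25, Anxa2 by 2.53 ± 0.24 and Cp by 2.76 ± 0.27.

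In total, 2162 of 13614 genes were higher and 1511 lower in IRV than in NV (edgeR, adjusted p under 0.05). With the library set as a covariate, 1080 were higher and 835 lower. Within the shallow libraries, IRV replicates 1 and 2 against NV gave 848 higher and 881 lower genes of 12892 tested, of which 827 and 789 were among the calls of the full comparison. With library totals as the only scaling, the median of all genes moved from -0.03 to 0.49 on the log2 scale, and the split became 5716 higher and 246 lower.

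Among the largest rises were Aoc1, a diamine oxidase, at 5.33 ± 0.51, Ubd, a ubiquitin-like modifier, at 5.63 ± 0.87, Cd14, a lipopolysaccharide co-receptor, at 4.92 ± 0.77, and Stra6, a retinol transporter, at 4.59 ± 0.54. Adamtsl4, Cd300c2 and Il2rb rose by 4.99 ± 0.80, 4.67 ± 0.96 and 4.65 ± 1.00. Mfap2, a microfibril protein, had no count in the 4 NV libraries and 4.89 ± 1.08 CPM in IRV. The largest falls included Aqp4, a basolateral water channel, at -3.54 ± 0.47, from 40.2 ± 9.84 to 4.75 ± 3.73 CPM. Mettl7a2 changed by -2.87 ± 0.73, Ceacam2 by -2.77 ± 0.79 and Necab1 by -3.39 ± 0.77. Stk-ps1, Apoo-ps, Dach2 and Methig1 were named by the same rule at -4.14 ± 1.14, -3.07 ± 0.93, -2.57 ± 0.90 and -2.52 ± 0.85. The first pair are pseudogenes whose counts cannot be separated with certainty from those of their parent genes. With the library set as a covariate these 4 genes had -2.25 ± 0.78, -2.39 ± 1.08, -1.15 ± 0.49 and -1.70 ± 1.00 (adjusted p = 0.062, 0.15, 0.13 and 0.29), and Mettl7a2 and Ceacam2 had -2.78 ± 1.05 and -2.32 ± 1.09 (0.085 and 0.18).

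Stromal and immune genes rose together. In the fibroblast and extracellular matrix list, 32 of 35 tested members rose, with a median of 1.98. Col1a1, a chain of type I collagen, rose by 3.11 ± 0.34, Mmp14 by 3.49 ± 0.35, Vim by 2.13 ± 0.22 and Dcn by 1.98 ± 0.20. In the macrophage and monocyte list, 19 of 24 rose, with Ctss, a lysosomal protease, at 3.64 ± 0.33, Cd14 as given above and C1qb at 3.01 ± 0.35. Complement had 15 of 20 members higher, among them Serping1 at 2.62 ± 0.26. The interferon response list had 19 of 29 higher, with Irf1 at 1.81 ± 0.28 and Psmb8 at 2.53 ± 0.41. Secretory phenotype factors had 22 higher and 2 lower of 33, with Timp2 at 2.42 ± 0.24. Of 8 tested lymphocyte genes 5 rose, Igkc by 6.02 ± 0.71 and Cd4 by 3.54 ± 0.65, although the list as a whole did not pass (adjusted p = 0.28). Of the 4 tested neutrophil genes Lcn2 rose, and Cxcr2 differed by -1.64 ± 0.85, Ltf by -1.04 ± 0.68 and Csf3r by 0.68 ± 0.59 without passing. Of 319 tested receptor genes 13 were lower in IRV.

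Genes of tubular transport and energy metabolism fell. In the proximal tubule list, 30 of 40 members were lower and none higher, with a median of -0.92. Slc34a1, the main apical phosphate transporter, changed by -1.11 ± 0.19, Slc13a3 by -1.22 ± 0.15 and Miox by -1.46 ± 0.20. In the respiratory chain and citric acid cycle list, 38 of 40 members were lower, with a median of -0.76; Cox4i1 changed by -0.95 ± 0.15. Fatty acid oxidation and peroxisome genes had 20 of 39 lower, with Acads at -0.89 ± 0.15. The NRF2 and antioxidant list had 20 lower and 1 higher of 37, with Gpx3 at -1.59 ± 0.22 and Cat at -1.01 ± 0.18. The list of NAD synthesis and use had 9 lower and 1 higher of 25, including Acmsd at -1.32 ± 0.26 and Nmrk1 at -0.84 ± 0.19.

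Of the genes and lists tied to senescence and PARP biology, Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.78 ± 0.39 (adjusted p = 0.0029). The senescence marker list had 7 of 21 members higher (adjusted p = 0.015, but 0.33 with an estimated correlation), and with the library set as a covariate its median went from 0.37 to 0.19 and its call was lost (adjusted p = 0.065). Gdf15 had 1.03 ± 1.21 CPM in NV and 1.85 ± 1.24 CPM in IRV, and Cdkn2a 0.225 ± 0.450 and 0.0710 ± 0.142 CPM, so both were below the filter. Parp1 differed by 0.18 ± 0.13 (adjusted p = 0.31) and Parp2 by 0.47 ± 0.33 (adjusted p = 0.30). The PARP family and ADP-ribose turnover list had 7 higher and 1 lower of 23, with Zc3hav1 at 1.34 ± 0.19 and Parp14 at 1.08 ± 0.19, both interferon-inducible. Its adjusted p was 0.021, and 0.33 with an estimated correlation; with the set as a covariate the call was lost (adjusted p = 0.23), while the median went from 0.24 to 0.21. Mki67, a marker of cycling cells, rose by 1.46 ± 0.29, with 7 of 20 proliferation genes higher.

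Further lists past the threshold were podocyte (11 of 15 higher), endothelium (6 of 20 higher), apoptosis (10 higher and 2 lower of 27) and immediate early and heat shock genes (13 higher and 2 lower of 22). With an estimated correlation each of these 4 had an adjusted p of 0.33, and none of the 28 lists passed, while 17 passed fry. With the set as a covariate the higher members were 9 for podocyte, 1 for endothelium, 6 for apoptosis (none lower), 6 for immediate early and heat shock (2 lower), 4 for proliferation, 3 for senescence and 4 for PARP genes, and 5 NAD genes were lower. Within the shallow libraries the first 5 of these counts were 5, 1, 5, 7 and 2, and the immediate early median went from 1.22 to 0.52. The endothelium list had an adjusted p of 0.065 with the set as a covariate, and its median went from 0.39 to 0.19. Lists that did not pass were loop of Henle and distal tubule (9 lower and 1 higher of 20; adjusted p = 0.11), collecting duct (0.75), p53 targets (0.092), DNA repair (0.13), glycolysis and hypoxia response (0.49), necroptosis, pyroptosis and ferroptosis (0.53), circadian clock (0.73), erythrocyte (0.54), and adipose, adrenal and muscle (0.13). With the set as a covariate, 5 lists that had not passed did so: loop of Henle (adjusted p = 0.00086), glycolysis (0.0049), circadian clock (0.0065), lymphocyte (0.0065) and adipose, adrenal and muscle (0.039). With an estimated correlation these 5 had 0.38, 0.32, 0.32, 0.32 and 0.39 in that fit. In the loop of Henle list, Egf changed by -1.64 ± 0.38 and Calb1 by -1.85 ± 0.43. In all, 18 of 28 lists passed camera at the preset correlation, 13 higher and 5 lower. Adjusted over the list alone, 22 tubular injury, 34 fibroblast and matrix, 20 macrophage, 23 interferon response and 10 senescence genes were higher, and 33 proximal tubule and 24 fatty acid oxidation genes lower. Going the other way were 2 senescence genes, 1 macrophage gene and 1 fatty acid oxidation gene. The collecting duct list had a median of -0.01 and a test direction of higher.

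**Figure D2:**
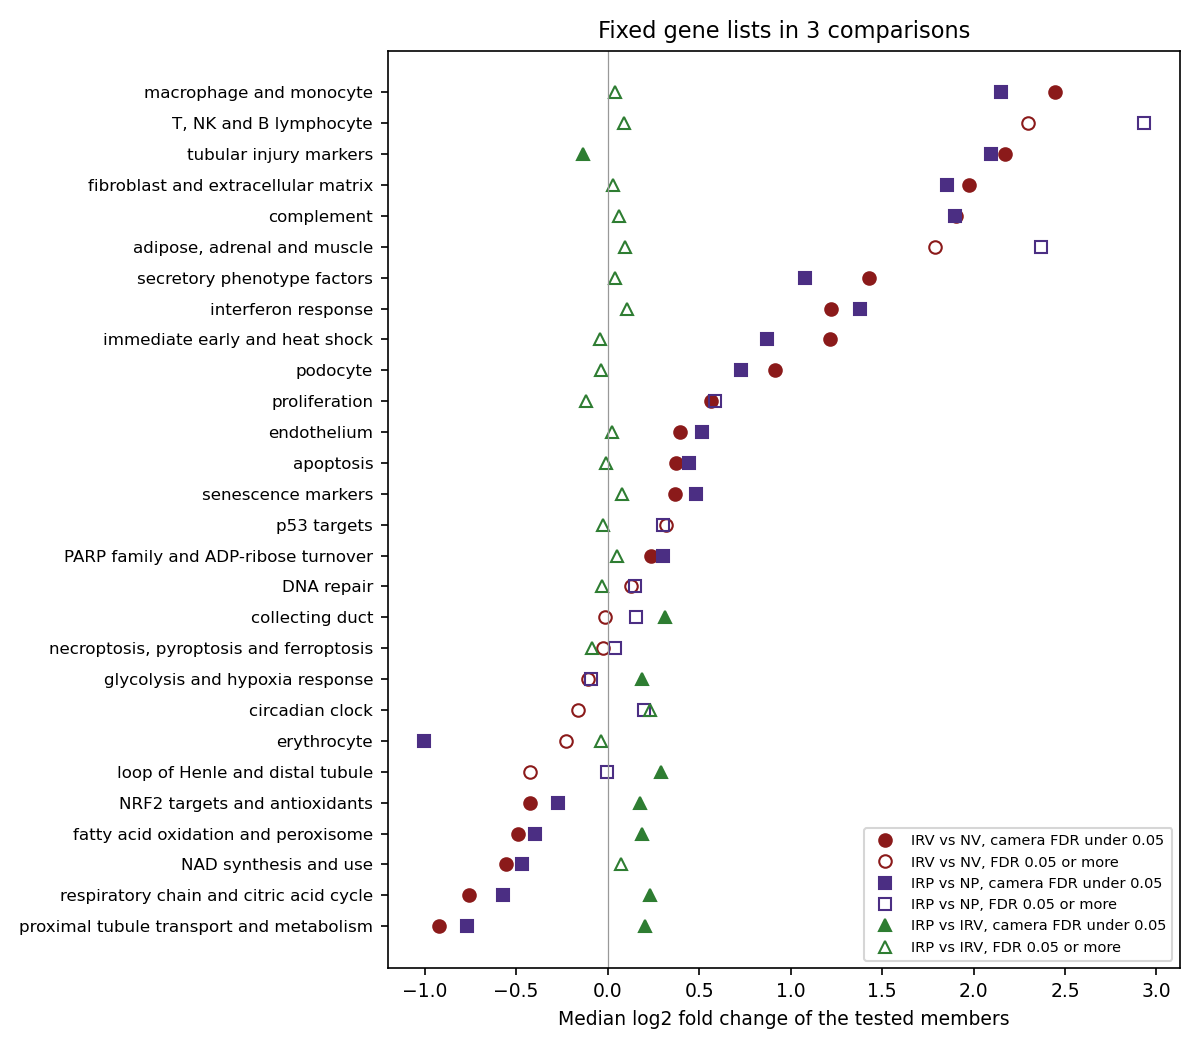
Median log2 fold change of the tested members of each fixed list (x axis) in IRV vs NV, IRP vs NP and IRP vs IRV. Filled symbols mark lists past camera at the preset correlation. Injury shifts of tubular injury markers lie at 2.17 and 2.10, and the IRP vs IRV median of that list at -0.13.

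The comparison of IRP with NP asked what the injury did under PJ34. Of the same marker groups, 21 of 22 tubular injury markers, 33 of 35 fibroblast and matrix genes and 19 of 24 macrophage genes were higher, with 1 macrophage gene lower. These 3 lists passed at the preset correlation but not with an estimated correlation (adjusted p = 0.36, 0.36 and 0.39). Havcr1 rose by 4.62 ± 0.65, Lcn2 by 4.08 ± 0.53, Clu by 2.14 ± 0.18, Aoc1 by 4.93 ± 0.49 and Igfbp2 by 5.83 ± 0.68. Mybpc2, a muscle protein gene, had no count in the 4 NP libraries and 7.42 ± 3.44 CPM in IRP. Rps3a2, a near copy of a ribosomal protein gene, had no count in NP and 18.8 ± 5.72 CPM in IRP, a difference that is uncertain because reads of such copies are shared. Ctss rose by 4.31 ± 0.36 and Cdkn1a by 2.67 ± 0.44. Proximal tubule genes had 25 of 40 members lower, including Slc13a3 at -1.10 ± 0.15 and Pck1 at -1.83 ± 0.30, and 37 of 40 respiratory chain genes were lower. With the library set as a covariate, 11 tubular injury, 25 fibroblast and matrix and 9 macrophage genes were higher, and 3 proximal tubule genes and 1 respiratory chain gene lower. The medians of these 5 lists were then 1.72, 1.55, 1.84, -0.86 and -0.61. Of the genes named by the rule in this comparison, 79 lost their call with the set as a covariate. A further 4 changed direction, and 44 were unchanged, called or not. The erythrocyte list was lower in this comparison (3 of 6 members; adjusted p = 0.047), with Hba-a1 at -1.27 ± 0.31, whose counts are shared with its near-identical copy. With an estimated correlation the list had an adjusted p of 0.39, and with the set as a covariate 0.32, its median going from -1.01 to -0.28. Adjusted over the list alone, 22 tubular injury and 34 fibroblast and matrix genes were higher and 28 proximal tubule genes lower.

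In all 2671 genes were higher and 3264 lower in IRP than in NP. The falls included all 319 tested receptor genes, with a median of -4.40, and the 8 largest falls by the rule were Htr2c at -6.98 ± 1.18, 6 receptor genes including Olfr1039 at -6.73 ± 1.36 and Vmn2r2 at -5.82 ± 0.88, and BC051077 at -5.75 ± 1.05. Every IRP library was deep and every NP library shallow. With the set as a covariate 343 genes were higher and 107 lower, and Htr2c, Olfr1039 and Vmn2r2 had -2.70 ± 1.26, -0.51 ± 1.12 and -2.21 ± 0.87 (adjusted p = 0.27, 0.88 and 0.18). With library totals as the only scaling 7012 were higher and 1778 lower. Of 28 lists, 18 passed at the preset correlation, none with an estimated correlation (lowest adjusted p = 0.36) and 20 with fry.

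The calls of the 2 injury comparisons overlapped. Of 2162 genes higher in IRV than in NV, 1798 were also higher in IRP than in NP, against 424.2 for independent lists. Of 1511 lower genes, 1055 were shared, against 362.3. The comparisons share no libraries. With IRV restricted to its shallow libraries, 780 of 846 higher and 604 of 878 lower genes were shared, against 165.9 and 219.6.

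The comparison of IRP with IRV asked whether PJ34 changed the injured kidney. No gene passed the threshold (edgeR), 1832 genes had an unadjusted p under 0.05 against 680.7 expected by chance, and the lowest adjusted p was 0.073. With the library set as a covariate no gene passed and 208 had an unadjusted p under 0.05. The 319 tested receptor genes had a median log2 difference of -3.09 without the covariate. Havcr1 was 65.2 ± 41.5 CPM in IRP and 110.5 ± 24.2 CPM in IRV, a log2 difference of -0.76 ± 0.36 with a 95% interval of -1.53 to 0.0046 (adjusted p = 0.38). Cdkn1a differed by -0.10 (-0.73 to 0.52), Lcn2 by -0.06 (-0.71 to 0.59), Col1a1 by 0.06 (-0.55 to 0.67), Mki67 by -0.12 (-0.62 to 0.38), Slc34a1 by 0.19 (-0.19 to 0.58) and Parp1 by 0.08 (-0.16 to 0.33). Gdf15 had 2.54 ± 0.998 CPM in IRP and 1.85 ± 1.24 CPM in IRV. Cdkn2a, with 8 counts over the IRP and 2 over the IRV libraries, had 0.274 ± 0.201 and 0.0710 ± 0.142 CPM, too few counts to read a direction from. Within the deep libraries no gene passed and 302 had an unadjusted p under 0.05. DESeq2 called 5 genes higher and 1277 lower on the same 13614 genes, and 28 higher and 3098 lower on all 40472 genes of the table, while limma-voom called 0. Without IRV replicate 3 or without IRV replicate 4, 1460 genes passed in each case, 1451 and 1447 of them lower; the IRV group then held fewer deep libraries.

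**Figure D3:**
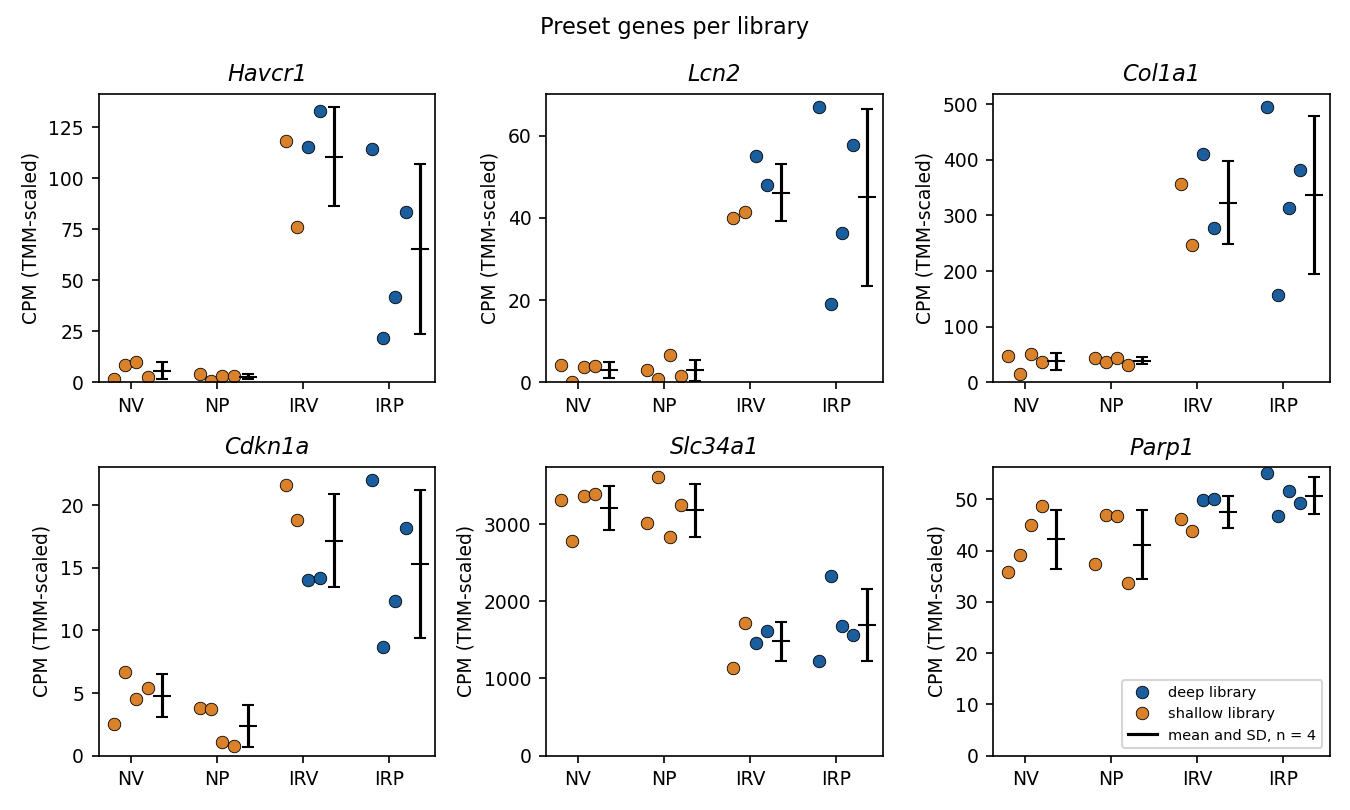
TMM-scaled CPM of 6 preset genes per library, by group and library set. Bars give mean and SD of 4 libraries. Havcr1 lies between 76.0 and 132.6 CPM in IRV and between 21.7 and 114.1 CPM in IRP.

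Several lists shifted by small amounts between IRP and IRV. At the preset correlation 8 of 28 lists passed. The respiratory chain list was higher (40 of 40 members with a positive sign, none past the threshold alone), with a median of 0.23 and an adjusted p of 1.85e-09. Fatty acid oxidation (median 0.19), NRF2 and antioxidants (0.17), glycolysis and hypoxia response (0.19), loop of Henle (0.29), collecting duct (0.32) and proximal tubule (0.20) were also higher. Tubular injury markers were lower, with a median of -0.13. No list passed with an estimated correlation (lowest adjusted p = 0.94) or with fry (0.89). Adjusted over the list alone, no gene of these 8 lists passed. Without IRP replicate 1, 17 lists passed, and without IRV replicate 3, 4 lists. Without IRP replicate 2 the respiratory chain list had an adjusted p of 0.055, and the tubular injury and proximal tubule lists changed direction, with adjusted p of 0.953 and 0.0748. Within the deep libraries 10 lists passed at the preset correlation. Proximal tubule (median from 0.20 to 0.13, adjusted p = 0.14) and NRF2 genes (0.17 to 0.08, adjusted p = 0.095) no longer did, while podocyte (-0.12), macrophage (-0.10) and immediate early genes (-0.20) were called lower and lymphocyte genes (0.30) higher. The respiratory chain list had a median of 0.17 there and tubular injury markers -0.24. An estimated correlation was not run within the deep libraries; with the set as a covariate it left no list (lowest adjusted p = 0.81).

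The injury score was 0.84 ± 0.29 in IRP and 0.60 ± 0.38 in IRV (SD, n = 4). The difference of 0.24 was within the spread between libraries (exact permutation p = 0.31, two-sided). Within the deep libraries the difference was -0.07 (exact permutation p = 0.73 over 15 assignments, smallest possible 0.067). IRV replicates 1 and 2, both shallow, had scores of 0.36 and 0.21, and IRV replicates 3 and 4, both deep, had 1.03 and 0.79. IRP replicate 2 had the lowest score of its group, 0.47.

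**Figure D4:**
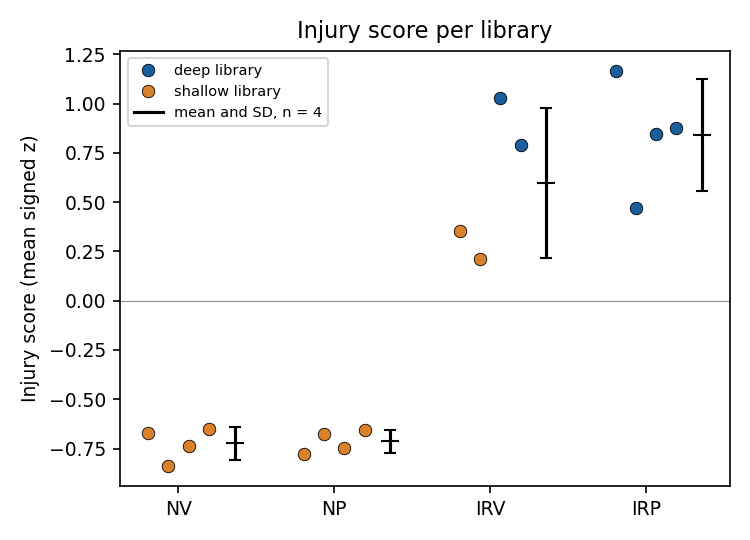
Injury score (mean signed z value over 7536 genes) per library, by group and library set, with mean and SD of 4 libraries. IRP libraries lie between 0.47 and 1.17, IRV libraries between 0.21 and 1.03, and uninjured libraries between -0.84 and -0.65.

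The comparison of NP with NV asked what PJ34 did without injury. No gene passed (edgeR), 501 genes had an unadjusted p under 0.05 against 680.7 expected by chance, and the lowest adjusted p was 0.16. DESeq2 called 4 genes, on the same genes and on all 40472, and limma-voom 0. Without NV replicate 3 and without NV replicate 4, 1 gene passed in each case. No list passed, the lowest adjusted p being 0.14 for erythrocyte genes, with a median of 0.53 and 2 genes higher when adjusted over the list alone. Without NV replicate 3, without NP replicate 1, with a replicate block and with library totals only, 1 list passed in each case. Pck1, a gluconeogenic enzyme, differed by 0.68 ± 0.29 and Sox9 by 1.13 ± 0.77, neither past the threshold. The injury score differed by 0.01 (exact permutation p = 0.94, two-sided, n = 4).

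The interaction asked whether PJ34 acted differently in injured and uninjured kidneys. No gene passed (edgeR), 1550 had an unadjusted p under 0.05 against 680.7 expected by chance, and the lowest adjusted p was 0.33. With the library set as a covariate 428 had an unadjusted p under 0.05. DESeq2 called 22 genes on the same 13614 genes, 21 of them lower, and 48 on all 40472, while limma-voom called 0. Without IRV replicate 3, 419 genes passed, 414 of them lower. Irf9, an interferon signalling factor, had a value of 1.04 ± 0.35 and Sirt5, a mitochondrial deacylase, -2.25 ± 0.79, which became -0.12 with the library set as a covariate. The respiratory chain, NRF2, fatty acid oxidation and loop of Henle lists were higher at the preset correlation, with medians of 0.20, 0.18, 0.14 and 0.33. None passed with an estimated correlation (lowest adjusted p = 0.98) or fry (0.96), and only the respiratory chain list passed with the set as a covariate (adjusted p = 0.0028), although the medians were then 0.19, 0.15, 0.11 and 0.29. Without IRV replicate 1, 1 list passed, without IRV replicate 3 or IRP replicate 2, 2 lists, and without IRP replicate 1, 7 lists.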

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

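The tests of the library set, of depth and of the respiratory chain list below were chosen after the results were seen, as was the count of absent genes as 0; the test of genomic DNA was written after the background was seen but before its ratio was computed.

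Counts over silent genes. In the 10 shallow libraries, chemosensory receptor genes summed to at least 8.09 times the CPM of any deep library, so sequencing depth alone, which CPM already divides out, cannot account for them. Genomic DNA was the first hypothesis: in male mice, with a single X chromosome, it would give X-linked silent genes fewer counts per kb than autosomal ones. Over 1258 protein-coding genes with at most 1 count in the deep libraries, the X to autosome ratio was 1.17 (95% bootstrap interval over genes 0.94 to 1.46). Counting genes missing from the deposited table as 0 gave 1.18 (0.90 to 1.5). The 19 autosomes, which have equal dose, ranged from 4.55 to 9.98 counts per kb, with X at 7.38. The bootstrap over genes holds no such spread between chromosomes, so the ratio is weak evidence against genomic DNA. Choosing genes by few counts in the deep libraries could also shift the ratio, which was not tested. The argument further requires that each mouse had a single X chromosome, as the labelled sex implies. That condition was not checked in the counts. No Y-linked gene was examined, and Xist was higher in the shallow libraries, as given below. A group of repeat-like gene models also took 13.2% to 25% of the counts in the shallow libraries and 0.73% to 1.49% in the deep ones. The X to autosome ratio does not cover these models, and what they say about genomic DNA was not tested. No biological explanation of the counts over silent genes was tested, since the pattern runs through the IRV group. Its source, genomic DNA included, stays open.

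Calls in IRP against NP. Genes called lower in this comparison were also lower in IRV replicates 3 and 4 than in IRV replicates 1 and 2. These libraries lie outside the comparison. The median log2 ratio was -1.29 (-1.43 to -1.13), against -1.66 in the comparison. In IRV replicates 1 and 2 against NV, all shallow, it was -0.25 (-0.27 to -0.22). The library set may thus account for most of these 3264 falls. For the 2671 higher genes these ratios were 0.25 (0.24 to 0.27) and 0.64 (0.60 to 0.67), against 0.90. By these medians the set is not the likely cause of most of these rises, and whether it adds a part stays open. The intervals in brackets were taken over genes and hold no spread between libraries. Every ratio rests on only 2 libraries, IRV replicates 1 and 2, on at least 1 side. Both readings thus rest on the medians alone and could change with other libraries. The library names of IRV replicates 1 and 2 and of replicates 3 and 4 fall into separate series, so the ratio between them also holds any difference between these series and not the set alone. The injury score is no separate evidence, since its genes come from a contrast in which 6 of the injured and 0 of the uninjured libraries were deep. A batch that follows the library numbers was tested with NP replicate 2, number 32, the uninjured library numbered next to the injured ones. Its score of -0.675 lay within the -0.838 to -0.649 of the other 7 uninjured libraries, but 1 library leaves this open. The deep libraries were numbers 35 to 40, and the shallow ones lay within 1 to 34. NP replicate 2 was shallow, so it cannot test a batch that begins at number 35. It also counted as uninjured when the score genes were chosen.

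Splits of the same 8 libraries into groups of 4 gave as many genes only for the real one of 35. This held for IRV against NV (3673 genes, highest other 2) and for IRP against NP (5935, highest other 37). A chance split is thus an unlikely source of these counts, but 1 in 35 is the smallest share possible, so chance is not excluded. Every other split mixed injured with uninjured libraries, which widens the spread within groups. For IRP against NP the real split also separates deep from shallow libraries. The set is excluded as the whole cause for IRV against NV, where 1729 genes passed within the shallow libraries. Of these, 827 higher and 789 lower ones were calls of the full comparison. That overlap is partly built in, since both use IRV replicates 1 and 2 and all NV libraries. For IRP against NP the set cannot be tested within the comparison, since all IRP libraries were deep and all NP libraries shallow. Its calls shared 780 of 846 higher and 604 of 878 lower genes with that shallow comparison, against 165.9 and 219.6 for independent lists. This overlap argues against the set as the whole cause, although the falls in IRP against NP went largely with the set. A batch that follows the library numbers would be shared by both comparisons and stays open. For IRP against IRV and NP against NV the real count was 0, so all 35 splits necessarily gave as many (highest other 2 in both), as did all 100 drawn for the interaction (highest other 2), and chance is not excluded there.

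Lists in IRP against IRV. The respiratory chain list remained past the threshold with the library set as a covariate (adjusted p = 3.78e-08, but 0.81 with an estimated correlation and 0.84 with fry in that fit), which argues against the set as the whole cause of the call at the preset correlation. Without IRP replicate 2, the library with the lowest injury score of its group and the highest mitochondrial share of all 16 (25.1%, against at most 19.1% in the other IRP and 17.9% in the IRV libraries), the adjusted p was 0.0553, so this 1 library, by milder injury or by whatever raised that share, may carry the call. The mean of the list per library, 4 against 4, gave an exact permutation p of 0.229, so spread between libraries of genes that vary together also stays open. An effect of PJ34 on these genes is a hypothesis that these libraries leave open. In the interaction, the same kind of difference was past the threshold for 4 lists, with adjusted p of 5.23e-05 for the respiratory chain, 0.00254 for NRF2, 0.00465 for fatty acid oxidation and 0.0247 for loop of Henle genes, but 0.98 with an estimated correlation and 0.96 with fry for each, and with the set as a covariate only the respiratory chain passed (the others 0.23, 0.063 and 0.063, while their medians went from 0.18, 0.14 and 0.33 to 0.15, 0.11 and 0.29, so the loss of the calls does not point to the set as their cause).

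Single libraries apart from their group were found in 12 of 168 group-wise checks, where 8.4 are expected by chance; the gap to the nearest library is given as a share of the group's range. In NV, replicate 4 had the highest total count (0.901). NV replicate 2 was high in the share of repeat-like gene models (0.837). It was low for Lcn2 (0.843), Slc34a1 (0.877), and the endothelium (0.898), interferon response (0.899) and respiratory chain (0.962) lists. Its Lcn2 value was 0 counts, against 4 or 5 in the other NV libraries, too few to read a departure from. In NP, replicate 2 was low for proliferation (0.856) and replicate 1 high for complement (0.849). IRV replicate 1 was low for the interferon response (0.832). In IRP, replicate 1 was low for collecting duct genes (0.905) and replicate 2 for lymphocyte genes (0.854).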

How the results depend on the processing

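The library set as a covariate, the restriction to shallow or deep libraries the filter at a mean CPM of 20 and DESeq2 on the genes edgeR tested were chosen after seeing the data. Genes past the threshold, 3673 in IRV against NV, were 5962 with library totals only, 6337 with limma-voom, 1915 with the set as a covariate and 1729 in the shallow libraries; leaving out 1 library gave 2483 to 4759. The 5935 of IRP against NP were 16733 without a filter, 13907 with a CPM of at least 1 in 4 libraries, 14565 with DESeq2 on all 40472 genes (5811 on the same 13614), 3126 at a mean CPM of 20 and 450 with the set as a covariate (5160 to 6443 leaving out 1 library). The 0 of IRP against IRV became 422 with library totals only, 1093 without a filter, 591 with a CPM of at least 1 in 4 libraries and 3126 with DESeq2 on all genes (1282 on the same 13614); leaving out 1 library gave 0 to 1460, the highest without IRV replicate 3 or 4. The 0 of NP against NV became 2 without a filter, 4 with DESeq2 on either set of genes and 3 with only the 2 groups in the fit (0 to 1), and the 0 of the interaction became 48 with DESeq2 on all genes and 22 on the same 13614 (0 to 419, the highest without IRV replicate 3). The looser filters and DESeq2 on all genes tested more genes, and otherwise the cause was not tested. DESeq2 was not run with the library set as a covariate. In IRP against IRV, the 319 tested receptor genes, which follow the set, had a median of -3.09 with edgeR. Genes with an unadjusted p under 0.05 there (edgeR) went from 1832 to 208 with the set as a covariate, against 680.7 expected by chance. The falls that DESeq2 called may thus follow the set and cannot be read as an effect of PJ34. Since 208 is fewer than chance gives, the fit with the covariate may be conservative. Its lack of calls is therefore weak evidence that PJ34 changed nothing. Lists past the threshold numbered 0 with an estimated correlation in every comparison. They were 0 with fry for IRP against IRV and the interaction, 1 with library totals only for NP against NV, and 1 with the set as a covariate for the interaction. Leaving out 1 library gave 17 to 19 lists for IRV against NV, 15 to 20 for IRP against NP, 4 (without IRV replicate 3) to 17 (without IRP replicate 1) for IRP against IRV, 0 to 1 for NP against NV and 1 to 7 for the interaction. Same-numbered replicates did not pair: their deviations correlated above 0.1 in 5 of 24 pairs, with a mean of -0.01. The replicate block gave 3675, 5805, 0, 0 and 0 genes in the order above and 20, 19, 9, 1 and 7 lists, and block p-values for the score of 0.38 and 1. Score differences passed in no setting, although the block (smallest possible p 0.125) and the deep libraries (0.067) could not have passed, at 0.10 to 0.39 for IRP minus IRV and -0.042 to 0.056 for NP minus NV when leaving out 1 library, and -0.071 for IRP minus IRV in the deep libraries. Direction turned, without a call, with library totals only for Lpcat3 in IRV against NV (0.034) and for Hadhb (0.050) and Gapdh (0.0029) in IRP against NP, and with the set as a covariate for Olfr427 (1.03), Cxcr2 (0.0027), Gsdme (0.50) and Aptx (0.21). Adjusted p of lists in IRP against IRV, leaving out 1 library, ran from 2.02e-08 to 0.953 for tubular injury, 3.45e-09 to 0.406 for proximal tubule, 5.23e-06 to 0.785 for fibroblast and matrix, 2.43e-06 to 0.824 for macrophage, 0.00137 to 0.794 for proliferation and 0.00328 to 0.953 for complement genes. These 6 turned direction without IRP replicate 2, the last 4 then being called higher at 5.23e-06, 0.00868, 0.00545 and 0.00328, and proximal tubule passing no longer at 0.0748. Cdkn2a, with at most 4 counts in any library, and Gdf15, with at most 24, were too low in count to be tested.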

Other observations

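Clock genes and the adipose, adrenal and muscle list were measured in both injury comparisons. In IRV against NV, Per2 changed by -1.33 ± 0.36, Hlf by -1.03 ± 0.18 and Tef by -0.78 ± 0.24, each past the threshold. The clock list had 1 member higher and 5 lower in IRV against NV (median -0.16, adjusted p = 0.73), and 3 higher and 4 lower in IRP against NP (median 0.20, adjusted p = 0.98). With the library set as a covariate it passed in both, at medians of -0.44 (adjusted p = 0.0065) and -0.49 (adjusted p = 0.0090), but not with an estimated correlation (0.32 and 0.30). Cfd and Fabp4, members of the adipose, adrenal and muscle list, rose in IRV against NV by 2.29 ± 0.64 and 1.00 ± 0.36. In IRP against NP they rose by 2.56 ± 0.64 and 1.49 ± 0.36. Cfd is also a member of the complement list, so its rise does not by itself point to fat cells. The adipose, adrenal and muscle list had 4 of 5 tested members higher in IRV against NV. With the library set as a covariate 1 was higher there, at a median of 1.90 against 1.79. In IRP against NP all IRP libraries were deep and all NP libraries shallow. In IRP against NP, Hba-a1 had an adjusted p of 0.0032, and with the set as a covariate its change went from -1.27 ± 0.31 to -1.02 ± 0.52 (adjusted p = 0.32).

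Xist, chosen after its values were seen, had 20.4 ± 8.92 CPM in NV, 20 ± 6.71 in NP, 12.3 ± 13.4 in IRV and 0.99 ± 0.52 in IRP, although the labels give all mice as male. It followed the library set, with 29.8 and 15.8 CPM in the shallow IRV replicates 1 and 2 and 1.28 and 2.43 CPM in the deep IRV replicates 3 and 4. Rab43, likewise chosen afterwards, had the lowest adjusted p of NP against NV (0.16), at 5.86 ± 5.34 CPM in NV and 32 ± 2.94 CPM in NP.

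A group of 7 repeat-like gene models, chosen after their values were seen, took 13.2% to 25% of the counts in the shallow libraries and 0.73% to 1.49% in the deep ones.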
